A study of Rattus norvegicus with 28 samples.

How the data were processed

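RNA was measured on Illumina rat bead arrays in 28 samples of C6, a rat glioma cell line used as a model of astrocytes. Cells were kept without serum for 24 h and then given 1 of 4 drugs at 25 µM for 2 h, or left untreated. The groups were untreated (6 arrays), desipramine (6), fluoxetine (6), haloperidol (6) and diazepam (4, with replicate numbers 1, 4, 5 and 6), and the labels call the replicates biological. No vehicle was stated for the untreated cells. Columns of 2 further arrays (4 columns in all) had no sample in the series and were not used.

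The authors read the arrays with GenomeStudio 1.9.0 and deposited a table they named non-normalized, in which each probe has on each array an intensity on a linear scale. The array medians of that intensity differed, so the values had not been scaled between arrays, and whether any background had been taken off was not stated. The same deposited table gives a detection p value (p_value) per probe and array, in steps of 1 in 825, which ranks the probe among the negative controls of its array. The authors also deposited normalized intensity values on a linear scale, whose method was not stated. The normalized values were used only as an alternative.

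Background correction and quantile normalization were done with the neqc function of limma 3.58.1 in R 4.3.3, with the mean and spread of the negative controls inferred from the detection p and an offset of 16. Probes with a detection p under 0.05 on at least 4 of the 28 arrays were kept, which left 11364 of 22523. Values are therefore log2 intensities, and fold changes of dim probes are pulled toward 1 by the offset. Probes were named by the symbols supplied for the series; 13793 probes carried 1 symbol and 8730 had none and appear under their probe identifier. For gene counts and list tests, each of 7958 named genes was represented by its probe with the highest mean over all arrays. No genome build came with the probes, so no positions are given.

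The arrays were fitted together in limma with 1 mean per group and no block, and the 9 comparisons were contrasts of those means. In these, "antidepressants" is the mean of the desipramine and fluoxetine groups and "non-antidepressants" is the mean of the haloperidol and diazepam groups. Arrays of 1 drug are not replicates of a drug class, so SE and p of these contrasts concern the drugs used and not their classes. Tests were two-sided, and p was adjusted by the Benjamini-Hochberg method over the probes kept, with 0.05 as the threshold. Errors of log2 changes are standard errors (SE) from this fit. Where no array of the lower group detected a gene, its fold is given only as a lower bound against the detection limit. Where few arrays of the lower group detected a gene, its log2 change is inexact: untreated cells detected Dusp8, Dusp4 and Cdkl1 on 2 of 6 arrays, fluoxetine cells Dlx3 on 3 of 6, diazepam cells Enc1 on 2 of 4 and antidepressant cells Cdkl1 on 5 of 12. The groups, comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined, apart from those tests and alternatives that are named as chosen later.

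The rule named, in each comparison with untreated cells and in antidepressants against non-antidepressants, the 8 largest rises and 8 largest falls past the threshold. Such genes had 1 symbol, were detected on every array of the higher group, and had every value of the higher group above the mean of the lower group. In the other 4 comparisons the 3 largest of each were named by the same rule, and for each gene list up to 4 members with the largest absolute change. A further set held probes changed the same way by both antidepressants that also differed between each antidepressant and each of haloperidol and diazepam. Its 10 largest mean changes were named.

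Gene lists were tested with camera (limma) at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. The p was adjusted over the 25 lists within a comparison. The lists covered cholesterol synthesis, fatty acid synthesis, immediate early genes, the integrated stress response, endoplasmic reticulum chaperones, heat shock, oxidative stress genes under Nrf2, hypoxia and glycolysis, growth and neurotrophic factors, cAMP and CREB targets, glucocorticoid targets, the circadian clock, lysosome and autophagy, NF-kappaB and inflammation, the cell cycle, p53 targets, regulators of MAP kinase and G protein signals, serotonin and noradrenaline genes, ribosomal proteins, oxidative phosphorylation, and markers of astrocytes, neurons, oligodendrocytes, microglia and endothelium. Several genes belong to more than 1 list, such as Sgk1, Per1, Dusp1, Ccn2 and Ptgs2.

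Whether the replicate number pairs the arrays was tested by correlating same-numbered arrays of different groups after removing group means. The lowest and highest of these correlations were 0.223 and 0.467 for untreated with desipramine, 0.104 and 0.508 for untreated with fluoxetine, and 0.139 and 0.462 for desipramine with fluoxetine. They were 0.285 and 0.420 for desipramine with haloperidol and 0.257 and 0.510 for fluoxetine with diazepam. In the other 5 pairs of groups the lowest was at or below 0.0614. By these lowest values the number pairs only some of the groups. The mean correlation of same-numbered arrays was nevertheless positive in every pair of groups, from 0.156 (haloperidol with diazepam) to 0.385 (fluoxetine with diazepam). Counts with the replicate number as a block are therefore given beside every comparison. The first principal component separated numbers 5 and 6 from 1 to 4 in every group, so counts of probes within each of these sets of numbers stand beside the pooled counts. Diazepam lacks numbers 2 and 3, so its comparisons are not balanced over the numbers.

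The pipeline was tested on simulated data, in which changes of 0.5 and 1 log2 units were planted into 100 probes each. For desipramine against untreated cells, 87% of the smaller and 99% of the larger changes were recovered with 8 false calls among 194, and for haloperidol against diazepam 63% and 99%. A list shifted by 0.3 was called by camera and 0 of the other lists. The simulated noise was independent between genes, equal in spread between groups, and free of any effect of the replicate number. The real arrays differed by number and in spread between groups, so these rates need not hold for them. Nor does the camera result test correlation between genes. The number of arrays limits the precision.

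Because all drugs were compared with the same untreated arrays, the overlap of 2 drugs was set beside the overlap when the untreated arrays were divided into 2 sets of 3, 1 set per drug (chosen later for 3 drugs, with 2 arrays each, and for 4 drugs, with 3 arrays per 2 drugs), and the correlation of their effects beside simulations of unchanged groups. Simulations of unchanged groups were planned for the overlap too, but such groups give almost no calls, so their overlap is near 0 by construction and is not reported. Alternatives planned in advance were other normalizations, the authors' normalized values, other filters on dim probes, the replicate number as a block, only the compared groups in the fit, another moderation of the variance, array weights, stricter thresholds, the mean over a gene's probes, and leaving out each array. A block for the chip could not be run, because the deposited tables do not name the chip. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.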

Results

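Gene expression was measured in C6 rat glioma cells after 2 h with an antidepressant (desipramine or fluoxetine), the antipsychotic haloperidol or the benzodiazepine diazepam, each at 25 µM, and in untreated cells. Desipramine is a tricyclic that inhibits noradrenaline and, less strongly, serotonin reuptake, and fluoxetine is a selective serotonin reuptake inhibitor. The design asks which genes respond to antidepressants of different classes in a cell line of glial character, and which of these responses the other drugs share. There were 6 arrays per group and 4 with diazepam. The mean number of probes detected per array was 10266 ± 210 (SD, n = 6) in untreated cells, 10091 ± 176 with desipramine, 10148 ± 206 with fluoxetine, 10212 ± 211 with haloperidol and 10136 ± 307 (n = 4) with diazepam.

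Arrays differed by replicate number as well as by drug. The first principal component held 18.7% of the variance and averaged 11.2 for arrays numbered 5 and 12.1 for those numbered 6, and between -9.64 and -1.24 for numbers 1 to 4. After each number's mean was removed, all 6 fluoxetine and 6 haloperidol arrays were closest to their own group's mean, as were 5 of 6 desipramine, 4 of 6 untreated and 2 of 4 diazepam arrays. Desipramine array 6 lay closest to the fluoxetine group.

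**Figure D1:**
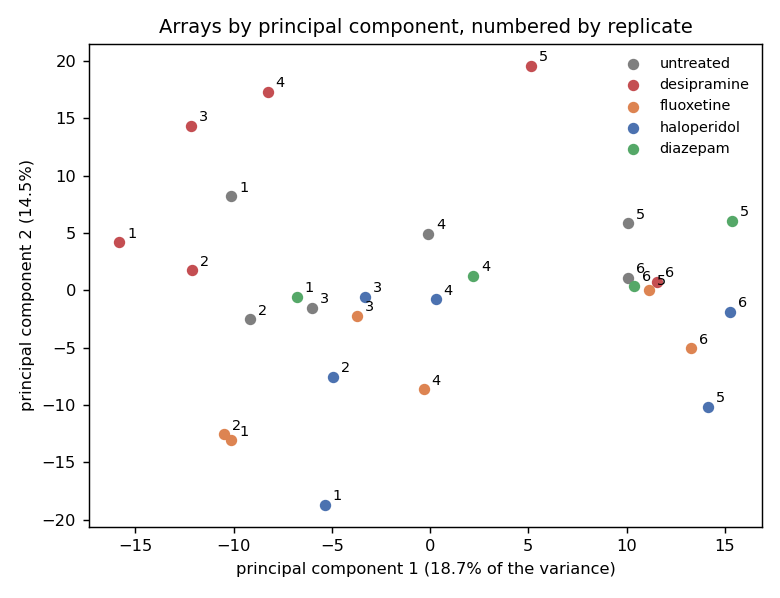
Scores of the 28 arrays on the first and second principal components of log2 intensity, coloured by group and numbered by replicate. Arrays numbered 5 and 6 lie to the right (means 11.2 and 12.1 on the first component), and desipramine arrays 3, 4 and 5 lie at the top.

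Desipramine raised Il1rl1, an interleukin receptor, more than any other named gene: its probe ILMN_1369374 was 5.07-fold higher than in untreated cells (log2 change 2.34 ± 0.30 SE, n = 6 and 6, adjusted p = 9.37e-06). Nppb, the precursor of brain natriuretic peptide, was 3.98-fold higher (log2 1.99 ± 0.27), and Bhlhe40, a transcriptional repressor tied to the circadian clock, 2.83-fold higher (adjusted p = 4.46e-09). Klf10, a zinc finger transcription factor, rose by 1.42 log2 units, and Spry4, an inhibitor of receptor tyrosine kinase signals, by 1.41. Sox8, the chemokine Ccl2 and Dmp1 rose by 1.29, 1.28 and 1.27. Falls were smaller: Rasl11b, a small GTPase, had a log2 change of -0.94 ± 0.16, the transcription factors Atoh8 and Zic2 of -0.90 and -0.87, and the Wnt receptor Fzd8 of -0.82 ± 0.09. Tfrc, the transferrin receptor, Abcd2, a peroxisomal transporter, Abcb9, a lysosomal peptide transporter, and Olig1, a transcription factor of the oligodendrocyte lineage, had log2 changes of -0.82, -0.77, -0.74 and -0.69.

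In all, 635 of 11364 probes passed the threshold between desipramine and untreated cells, 383 higher and 252 lower, of which 26 were at least 2-fold higher and 0 at least 2-fold lower. With the replicate number as a block 1105 passed. Arrays numbered 1 to 4 alone gave 479, and arrays numbered 5 and 6 alone gave 0 in limma (842 at an unadjusted p under 0.05); 471 of the 479 changed in the same direction in arrays numbered 5 and 6. Under median scaling 245 passed, of which 33.1% were higher against 60.3% with quantile normalization, and with array weights 1058 passed. The desipramine arrays were uneven: Il1rl1 averaged 8.01 ± 1.19 (SD, n = 6) log2 units with desipramine and 5.67 ± 0.17 in untreated cells. For Nppb the SD was 1.02 with desipramine and 0.08 in untreated cells. The fit pools the spread of all groups, so for such genes the SE and adjusted p of desipramine comparisons understate the error.

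**Figure D2:**
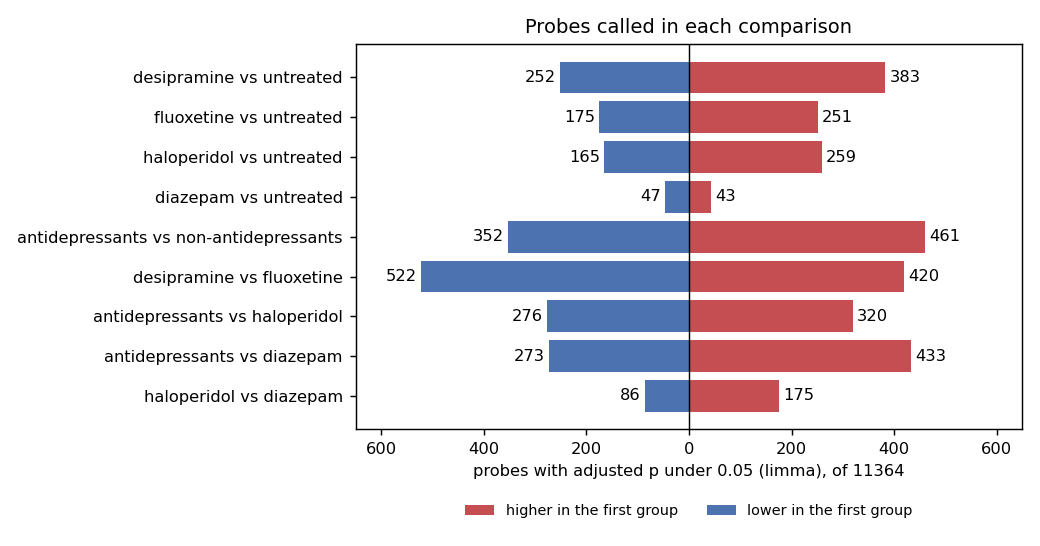
Number of probes past an adjusted p of 0.05 in each comparison, with probes higher in the first group to the right and lower ones to the left. Desipramine against fluoxetine had the most, 420 higher and 522 lower, and diazepam against untreated cells the fewest, 43 and 47.

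Of the 25 gene lists, 12 were called with desipramine by camera, 10 upward and 2 downward, and 7 of them also with an estimated correlation. Among immediate early genes, which respond to stimuli within minutes to hours, 15 of 27 measured members rose and 3 fell (adjusted p = 2.26e-13; 17 and 3 adjusted over the list alone). Ptgs2, which encodes the inducible cyclooxygenase, rose by 1.21 ± 0.19 log2 units, Ier3 by 1.07 and Ier2 by 1.02. The integrated stress response list, genes under Atf4 and Ddit3, had 12 of 20 members higher and 0 lower (adjusted p = 1.38e-13; 13 adjusted over the list alone), with Trib3 at 1.17 ± 0.18, Chac1 at 1.08 and Gadd45a at 0.71. In the list of NF-kappaB and inflammation, 10 of 15 rose and 0 fell (adjusted p = 7.48e-13; 11 adjusted over the list alone), among them the chemokines Ccl2 and Ccl7, at 1.28 and 1.10 log2 units. Regulators of MAP kinase and G protein signals had 5 of 17 higher and 2 lower (adjusted p = 0.000245; 8 and 2 adjusted over the list alone), with the phosphatases Dusp8 (0.93), Dusp6 (0.87) and Dusp4 (0.83) higher.

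Growth and neurotrophic factors had 4 of 17 higher with desipramine and 1 lower (adjusted p = 0.00135; 8 and 1 adjusted over the list alone), led by Hbegf, a ligand of the EGF receptor, at 0.79 ± 0.16. Inhba, at 0.87 ± 0.28, did not pass (adjusted p = 0.0649). Of cAMP and CREB targets 5 of 17 rose and 2 fell (adjusted p = 0.00114; 7 and 2 adjusted over the list alone): the kinase gene Sgk1 rose by 0.81 ± 0.08 and Fos by 0.75, while Dusp1, a MAP kinase phosphatase, had a log2 change of -0.64 ± 0.13. Of circadian clock genes 3 of 11 rose (adjusted p = 0.00169; 3 adjusted over the list alone), with Bhlhe40 far ahead of Per1 (0.43 ± 0.11). All 7 of these lists passed with an estimated correlation, where their adjusted p ranged from 0.000316 to 0.00495.

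The other 5 lists called with desipramine missed the threshold with an estimated correlation. Oxidative stress genes under Nrf2 had 2 of 15 members higher (adjusted p = 0.0122; 4 adjusted over the list alone; adjusted p = 0.0763 with an estimated correlation), and Hmox1, heme oxygenase, rose by 1.06 ± 0.11. Cholesterol synthesis had 3 of 17 higher, 4 adjusted over the list alone (adjusted p = 0.0122; adjusted p = 0.201 with an estimated correlation), including Idi1 and Stard4 at 0.45 and 0.44, and lost its call without untreated array 1 (adjusted p = 0.057), without desipramine array 6 (0.0716) and under median scaling (0.153). Glucocorticoid targets had 3 of 12 higher and 1 lower, 6 and 2 adjusted over the list alone (adjusted p = 0.0235; adjusted p = 0.0763 with an estimated correlation), and lost the call without desipramine array 6 (0.111). The cell cycle list was called downward with 1 of 26 higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.00353; adjusted p = 0.432 with an estimated correlation). The member that rose was Ccnd1, the cyclin of early G1 phase, at 0.55 ± 0.09. Astrocyte markers were called downward with 0 of 10 members past the threshold and 0 adjusted over the list alone, at a median of -0.13 (adjusted p = 0.039; adjusted p = 0.0763 with an estimated correlation). The astrocyte call was lost without desipramine array 2, 3 or 6 or untreated array 1, 2 or 4, at adjusted p from 0.0509 to 0.078.

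With fluoxetine the 2 largest rises among the named genes were in members of the integrated stress response list. Chac1, an enzyme that degrades glutathione, was 5.00-fold higher than in untreated cells (probe ILMN_1368718, log2 change 2.32 ± 0.16 SE, n = 6 and 6, adjusted p = 2.47e-11), and Trib3, a pseudokinase, 3.93-fold higher (log2 1.97 ± 0.18). The secreted stress cytokine Gdf15 was detected on all 6 fluoxetine arrays and on 0 of 6 untreated arrays, and was at least 2.58-fold higher. Fhl2, a LIM domain protein, rose by 1.65 ± 0.09 log2 units, the phosphatase Dusp8 by 1.65, the transcription factor Atf3 by 1.60, the ephrin receptor Epha2 by 1.59 and Rnd3 by 1.57. The largest falls were in Rasd1, a Ras-like G protein (log2 -1.36 ± 0.12), the chemokine receptor Cxcr4 (-1.25 ± 0.20), Rasl11b (-1.21) and the homeobox gene Dlx3 (-1.14). Id1, an inhibitor of basic helix-loop-helix factors, had a log2 change of -0.93, Dlx1 of -0.80, the proapoptotic gene Bmf of -0.74 and Socs1, a suppressor of cytokine signals, of -0.75 ± 0.22 (adjusted p = 0.047). The Socs1 call was lost without any of fluoxetine arrays 3 to 6 or untreated arrays 1 to 3, at adjusted p from 0.0628 to 0.149.

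Between fluoxetine and untreated cells 426 probes passed, 251 higher and 175 lower, with 23 at least 2-fold higher and 5 at least 2-fold lower. Those 5 were the probes of Rasd1, Cxcr4, Rasl11b and Dlx3 and the unnamed probe ILMN_1350597, the last named after its value was seen. With the replicate number as a block 861 passed. Arrays numbered 1 to 4 alone gave 305 and those numbered 5 and 6 gave 25, and 299 of the 305 changed in the same direction in the latter. Median scaling left 158, and leaving out all arrays numbered 1, an alternative chosen after the data were seen, left 283.

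**Figure D3:**
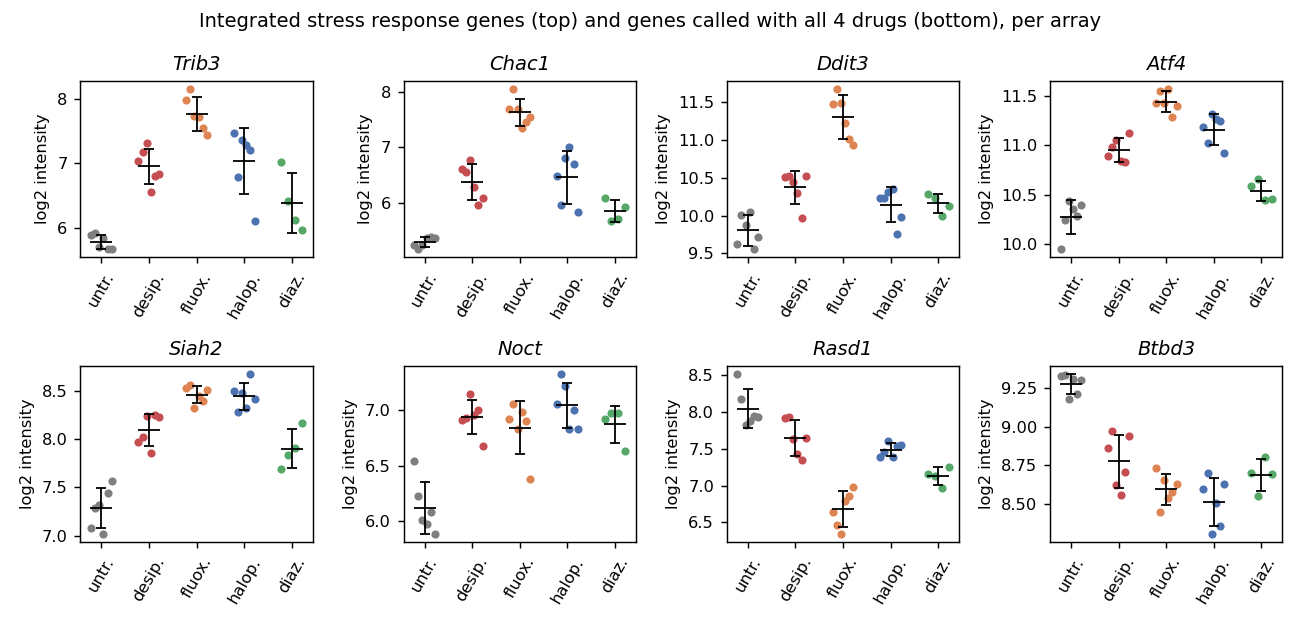
Log2 intensity per array (points), with mean and SD (bars), of integrated stress response genes in the top row and of genes past the threshold with all 4 drugs in the bottom row. Chac1 and Trib3 were 2.32 and 1.97 log2 units above untreated cells with fluoxetine, and Btbd3 was below untreated cells with each drug.

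The integrated stress response list had 12 of 20 members higher with fluoxetine and 0 lower (adjusted p = 2.01e-25; 13 adjusted over the list alone), among them Ddit3, which encodes the factor CHOP, 2.83-fold higher and Ppp1r15a, a phosphatase subunit, higher by 1.27 ± 0.09 log2 units. Of immediate early genes 11 of 27 rose (adjusted p = 1.21e-15; 15 adjusted over the list alone), led by Atf3 and the matrix-associated genes Ccn1 and Ccn2, at 1.35 and 1.33. Glucocorticoid targets had 7 of 12 higher (adjusted p = 2.6e-08; 8 adjusted over the list alone), with Sgk1 at 0.96 ± 0.08 and the clock gene Per1 at 0.83 ± 0.11. Of circadian clock genes 4 of 11 rose (adjusted p = 3.88e-08; 5 adjusted over the list alone), led by the repressor Nfil3 at 1.49 ± 0.11 and followed by Per1, Bhlhe40 (0.75) and Nr1d1 (0.74). Regulators of MAP kinase and G protein signals had 6 of 17 higher (adjusted p = 3.75e-07; 8 adjusted over the list alone), with Dusp10 at 1.15 ± 0.09. Of cAMP and CREB targets 3 of 17 rose (adjusted p = 1.58e-05; 6 adjusted over the list alone), namely Sgk1, Per1 and Gem (0.77). Growth and neurotrophic factors had 4 of 17 higher (adjusted p = 0.00489; 5 adjusted over the list alone), including Ccn2 and the neurotrophin gene Bdnf at 0.64 ± 0.09. These 7 lists passed with an estimated correlation, at adjusted p from 3.4e-05 to 0.0115.

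The other 5 of the 12 lists called with fluoxetine did not pass with an estimated correlation. NF-kappaB and inflammation genes had 4 of 15 higher, 7 higher and 1 lower adjusted over the list alone (adjusted p = 4.39e-05; adjusted p = 0.116 with an estimated correlation), with the chemokine Cxcl1 at 1.24 ± 0.26. The cell cycle list was called downward with 2 of 26 lower, 2 adjusted over the list alone (adjusted p = 0.00387; adjusted p = 0.512 with an estimated correlation), the larger fall being in cyclin gene Ccne2 (-0.61 ± 0.14), and lost its call without fluoxetine array 4 (0.0509). Cholesterol synthesis had 0 of 17 past the threshold, 3 adjusted over the list alone, and a median of 0.12 (adjusted p = 0.0401; adjusted p = 0.382 with an estimated correlation). Its call was lost without fluoxetine array 1, 3 or 6 or untreated array 1, at 0.0543 to 0.182. Hypoxia and glycolysis genes had 1 of 18 higher, 2 adjusted over the list alone (adjusted p = 0.0455; adjusted p = 0.6 with an estimated correlation), and lost the call without fluoxetine array 4, 5 or 6 or untreated array 1, 2 or 5, at 0.0501 to 0.394. Oxidative phosphorylation genes were called downward with 0 of 21 past the threshold, 0 adjusted over the list alone, and a median of -0.07 (adjusted p = 0.0297; adjusted p = 0.382 with an estimated correlation), and lost the call without fluoxetine array 4, 5 or 6, at 0.0548 to 0.0919.

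Haloperidol also raised Trib3 and Chac1 of the integrated stress response, 2.38-fold and 2.23-fold over untreated cells (log2 changes 1.25 ± 0.18 and 1.16 ± 0.16 SE, n = 6 and 6, adjusted p = 7.39e-05 and 3.22e-05). Wfikkn1, a secreted protein with protease inhibitor domains, rose 2.30-fold (log2 1.20 ± 0.13), the ubiquitin ligase gene Siah2 2.23-fold (1.16 ± 0.09) and Gnrh1, the gonadotropin-releasing hormone, 2.20-fold (1.14 ± 0.13). Ctsk, the protease cathepsin K, rose by 1.02 log2 units, the kinase gene Cdkl1 by 1.00 and Chka, a choline kinase, by 0.94. Rxfp3, a relaxin family receptor, had the largest fall, 2.82-fold (adjusted p = 0.000378), followed by Cxcr4 (-0.91) and Rasl11b (-0.80). Btbd3, Bmf, Slitrk6, the chemokine receptor-like gene Ccrl2 and Lurap1l had log2 changes of -0.76, -0.76, -0.74, -0.73 and -0.70.

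Haloperidol and untreated cells differed at 424 probes, 259 higher and 165 lower, with 7 at least 2-fold higher and 1, that of Rxfp3, at least 2-fold lower. Arrays numbered 1 to 4 alone gave 220 and arrays numbered 5 and 6 alone 9, and 217 of the 220 changed in the same direction in the latter. The count was 848 with the replicate number as a block, 84 under median scaling and 245 without the arrays numbered 1.

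Cholesterol synthesis genes rose with haloperidol: 5 of 17 passed and 12 did when adjusted over the list alone, with 0 lower (adjusted p = 1.82e-06; adjusted p = 0.0367 with an estimated correlation). Idi1, an isomerase of the mevalonate pathway, rose by 0.52 ± 0.11 log2 units, Sc5d, a sterol desaturase, by 0.46 ± 0.09 and Sqle, squalene epoxidase, by 0.38 ± 0.08. Each of these single genes missed the threshold under median scaling. The list kept its call, but camera can hardly respond to a shift of all probes, so this says little about scaling. Of the integrated stress response list 8 of 20 rose and 0 fell (adjusted p = 6.6e-11; 11 adjusted over the list alone), including Atf4, the factor that drives this response, at 0.88 ± 0.08 and Ppp1r15a at 0.75. Of circadian clock genes 3 of 11 rose (adjusted p = 0.00177; 4 adjusted over the list alone), with Nfil3 at 0.73 ± 0.11 and Per1 at 0.70 ± 0.11. Those 3 lists passed with an estimated correlation.

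A further 3 lists called with haloperidol did not. Glucocorticoid targets had 3 of 12 higher, 5 adjusted over the list alone (adjusted p = 0.0113; adjusted p = 0.0543 with an estimated correlation), including Per1 and Errfi1, a feedback inhibitor of the EGF receptor, at 0.51 ± 0.11. Astrocyte markers were called downward with 0 of 10 past the threshold, 3 adjusted over the list alone, at a median of -0.17 (adjusted p = 0.0249; adjusted p = 0.0543 with an estimated correlation), and lost the call without untreated array 2 (0.0627). Neuron markers had 3 of 9 lower, 3 adjusted over the list alone (adjusted p = 0.0393; adjusted p = 0.0666 with an estimated correlation), with the neurofilament gene Nefl at -0.40 ± 0.08. That call was lost without haloperidol array 4 or untreated array 2 or 6, at 0.0576 to 0.0666.

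With diazepam, Sik1, a salt-inducible kinase under cAMP control, was 1.97-fold higher than in untreated cells (log2 change 0.98 ± 0.19 SE, n = 4 and 6, adjusted p = 0.00597), Noct, a circadian phosphatase gene, 1.69-fold higher (0.75 ± 0.13) and Rgs2, a regulator of G protein signals, 1.64-fold higher (0.71 ± 0.14). Hexim1, an inhibitor of transcription elongation, Errfi1, Siah2, Cdkl1 and Larp1b rose by 0.65, 0.65, 0.62, 0.59 and 0.50 log2 units. Falls were larger: Ccrl2 was 2.31-fold lower (log2 change -1.21 ± 0.13, adjusted p = 1.71e-06) and the transcription factor gene Foxa2 2.11-fold lower (-1.07 ± 0.17). Rasd1, the protocadherin Pcdh18, the arylsulfatase Arsj, Enc1, the nuclear receptor Pparg and Hs3st1, a heparan sulfate sulfotransferase, had log2 changes of -0.92, -0.81, -0.79, -0.79, -0.75 and -0.72. The calls for Hexim1, Larp1b and Enc1, all at adjusted p above 0.04, were lost without most single arrays. For Hexim1 these were untreated arrays 1 to 6 and diazepam arrays 4 and 5 (0.0539 to 0.219), for Larp1b untreated arrays 2 to 5 and diazepam arrays 4 to 6 (0.0745 to 0.218), and for Enc1 untreated arrays 1 to 4 and diazepam arrays 4 to 6 (0.0507 to 0.254). Without diazepam array 5 the calls for Rgs2 (0.0508) and Hs3st1 (0.0666) were lost too.

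In total 90 probes passed between diazepam and untreated cells, 43 higher and 47 lower, with 0 at least 2-fold higher and 3 at least 2-fold lower. Those 3 were the probes of Ccrl2 and Foxa2 and the unnamed probe ILMN_1366573, the last named after its value was seen. Within numbers 1 to 4 the count was 17 and within numbers 5 and 6 it was 2, and all 17 changed in the same direction in the latter. With the replicate number as a block 172 passed. Without diazepam array 5, and likewise without diazepam array 6, 47 passed, and 48 did with only the diazepam and untreated groups in the fit. Median scaling, which moved the median log2 change of all probes to -0.115, left 21 probes, of which 9.52% were higher against 47.8% with quantile normalization, and ended the calls for all 8 rises named above and for Arsj and Enc1. Among the authors' normalized values 34.7% of the probes that passed were higher.

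Of the gene lists, 5 were called with diazepam, and 3 of these also with an estimated correlation. The integrated stress response list was called upward (adjusted p = 1.29e-06; adjusted p = 0.0446 with an estimated correlation) with 0 of 20 members past the threshold over all probes and 9 adjusted over the list alone, at a median of 0.21; Trib3 stood at 0.60 ± 0.20 and Chac1 at 0.55 ± 0.18. Under median scaling the mean change of this list was 0.08 ± 0.17 (SE). Of cAMP and CREB targets 3 of 17 rose (adjusted p = 0.000509; 6 higher and 1 lower adjusted over the list alone), among them Sik1 and Rgs2. Glucocorticoid targets had 1 of 12 higher, Errfi1 (adjusted p = 0.000518; 4 adjusted over the list alone). The call for cholesterol synthesis rested on 0 of 17 members, 0 adjusted over the list alone, at a median of 0.11 (adjusted p = 0.00711; adjusted p = 0.281 with an estimated correlation), and was lost without diazepam array 1 (0.123) or untreated array 1 (0.0835) and under median scaling (0.439). The cell cycle list was called downward with 0 of 26 members, 0 adjusted over the list alone, at a median of -0.07 (adjusted p = 0.0477; adjusted p = 0.728 with an estimated correlation). That call was lost without diazepam array 4 or 5 or untreated array 2, 3, 5 or 6, at 0.0819 to 0.482.

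**Figure D4:**
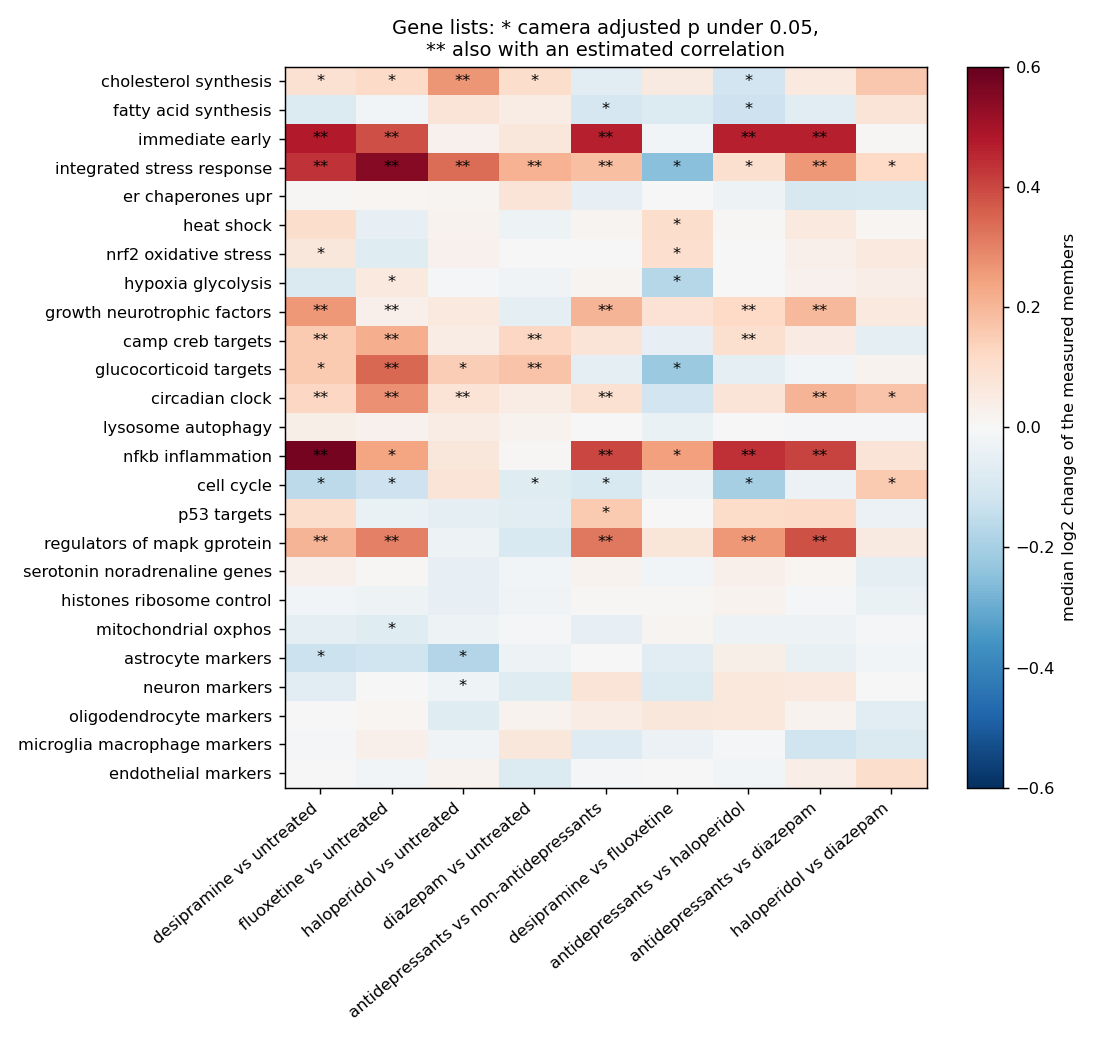
Median log2 change of the measured members of the 25 gene lists in the 9 comparisons, with stars for lists called by camera. The integrated stress response list was called upward with each of the 4 drugs, with medians from 0.21 (diazepam) to 0.55 (fluoxetine).

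Against the mean of haloperidol and diazepam, the antidepressants together were higher in genes of the inflammation, growth factor and immediate early lists. The SE and p of this contrast count arrays and not drugs, so they do not extend to antidepressants as a class. Il1rl1 was 2.78-fold higher (log2 change 1.47 ± 0.23 SE, 12 against 10 arrays, adjusted p = 5.12e-05), mainly through desipramine, since its log2 change against untreated cells was 2.34 with desipramine and 0.66 with fluoxetine (adjusted p = 0.279). The pooled spread, widened by desipramine, enters that fluoxetine test. Every fluoxetine array (6.09 to 6.48) lay above every untreated array (5.39 to 5.89). The chemokine Cxcl1 was 2.55-fold higher (1.35 ± 0.20) and Inhba, a subunit of activin, 2.38-fold higher (1.25 ± 0.21). Epha2, Ccn2, Dusp8, Rnd3 and Serpinb2, an inhibitor of plasminogen activators, followed at 1.22, 1.20, 1.15, 1.07 and 1.06. Zic2 had the largest negative difference, 2.00-fold (adjusted p = 3.79e-05), followed by Hexim1 (-0.93 ± 0.11) and Smad6, an inhibitor of bone morphogenetic protein signals (-0.76 ± 0.09). Id1, Cdkl1, Id2, the kinase gene Tesk2 and Fzd8 had log2 changes of -0.75, -0.71, -0.67, -0.67 and -0.66. These differences, positive or negative, lie between drugs and need not be changes from untreated cells. Diazepam lowered Ccn2 against untreated cells (log2 change -0.59, limma adjusted p = 0.000769), which widened its difference. Cdkl1 averaged 5.16 with the antidepressants and 5.07 in untreated cells, and rose by 1.00 with haloperidol and 0.59 with diazepam. Hexim1 averaged 7.43 with the antidepressants and 7.82 in untreated cells, and rose by 0.65 with diazepam. Of these 16 genes Il1rl1, Ccn2, Dusp8, Rnd3 and Cdkl1 also differed between desipramine and fluoxetine. The contrast passed at 813 probes, 461 higher and 352 lower. Within numbers 1 to 4 the count was 453 and within numbers 5 and 6 it was 67, with 441 of the 453 changed in the same direction in the latter. The replicate number as a block gave 1276 and median scaling 255, with 69.4% higher against 56.7%.

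In that contrast 9 lists were called. Immediate early genes had 18 of 27 higher and 2 lower (adjusted p = 2.71e-18; 19 and 3 adjusted over the list alone), with Ptgs2 at 0.97 ± 0.14, the transcription factor gene Myc at 0.96 ± 0.06 and Klf10 at 0.89. Against untreated cells Myc rose by 0.73 with desipramine and 0.74 with fluoxetine, and had a log2 change of -0.47 with diazepam. NF-kappaB and inflammation genes had 9 of 15 higher (adjusted p = 1.15e-12; 11 adjusted over the list alone), with Ccl7 at 1.04 and Ccl2 at 0.98. Regulators of MAP kinase and G protein signals had 9 of 17 higher and 2 lower (adjusted p = 5.37e-08; 9 and 2 adjusted over the list alone), including Spry4 (1.04), Spry2 (0.89) and Dusp6 (0.82), which act as feedback inhibitors. Genes of the integrated stress response were higher for 8 of 20 (adjusted p = 3.19e-08; 11 adjusted over the list alone), growth and neurotrophic factors 7 of 17 (adjusted p = 3.89e-06; 10 adjusted over the list alone) and circadian clock genes 3 of 11 (adjusted p = 0.000522; 5 adjusted over the list alone). These 6 passed with an estimated correlation, at adjusted p from 2.71e-05 to 0.0122.

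The 3 others in that contrast did not. The cell cycle list was called downward, with 1 of 26 higher and 5 lower, 1 and 7 adjusted over the list alone (adjusted p = 0.000522; adjusted p = 0.397 with an estimated correlation). Fatty acid synthesis had 2 of 12 lower, 2 adjusted over the list alone (adjusted p = 0.0141; adjusted p = 0.397 with an estimated correlation), the larger change in Acly, which makes acetyl-CoA from citrate (-0.26 ± 0.05), and lost the call without haloperidol array 1 (0.0548). The p53 targets had 2 of 8 higher and 1 lower, 2 and 1 adjusted over the list alone (adjusted p = 0.0417; adjusted p = 0.0689 with an estimated correlation), with Gadd45a at 0.62 ± 0.09. The p53 call was lost without desipramine array 2, fluoxetine array 1, haloperidol array 2 or 4 or diazepam array 5, at 0.0501 to 0.0777.

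The antidepressants also differed from each other. Dmp1, a matrix protein of mineralized tissue, was 3.37-fold higher with desipramine than with fluoxetine (log2 change 1.75 ± 0.24 SE, n = 6 and 6, adjusted p = 1.52e-05), Nppb 3.20-fold higher (1.68 ± 0.27) and the semaphorin gene Sema7a 3.11-fold higher (1.63 ± 0.22). Higher with fluoxetine were Ccn1 (log2 -1.41 ± 0.18), Nfil3 (-1.36 ± 0.11) and Gnrh1 (-1.32 ± 0.13). Of the 942 probes past the threshold, 420 were higher with desipramine and 522 with fluoxetine. The replicate number as a block gave 1485. Numbers 1 to 4 alone gave 880 and arrays numbered 5 and 6 alone 0 in limma (751 at an unadjusted p under 0.05), where 836 of the 880 changed in the same direction. Leaving out desipramine array 3 gave 614, leaving out desipramine array 4 gave 605, and median scaling gave 354, with 24.0% higher against 44.6%.

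Between the antidepressants 6 lists were called, and 0 of them with an estimated correlation. Lower with desipramine were the integrated stress response list, with 6 of 20 lower and 1 higher (adjusted p = 0.000164; 8 and 1 adjusted over the list alone; adjusted p = 0.144 with an estimated correlation), including Chac1 (-1.25 ± 0.16) and Ddit3 (-0.93 ± 0.12). Hypoxia and glycolysis genes had 4 of 18 lower, 8 adjusted over the list alone (adjusted p = 0.000958; adjusted p = 0.369 with an estimated correlation), with Adm, adrenomedullin, at -0.64 ± 0.15 and Bnip3 at -0.57 ± 0.11. Glucocorticoid targets had 5 of 12 lower, 6 lower and 2 higher adjusted over the list alone (adjusted p = 0.00463; adjusted p = 0.0843 with an estimated correlation), with Dusp1 at -0.94 ± 0.13. Higher with desipramine were oxidative stress genes under Nrf2, 4 of 15 higher and 1 lower, 6 and 1 adjusted over the list alone (adjusted p = 0.00227; adjusted p = 0.0843 with an estimated correlation), with Nqo1 at 0.73 ± 0.14 and Gclc, of glutathione synthesis, at 0.73 ± 0.12. NF-kappaB and inflammation genes had 4 of 15 higher and 1 lower, 5 and 1 adjusted over the list alone (adjusted p = 0.00227; adjusted p = 0.352 with an estimated correlation), with Ccl2 at 1.05 ± 0.21. Heat shock genes had 2 of 11 higher, 3 adjusted over the list alone (adjusted p = 0.0361; adjusted p = 0.144 with an estimated correlation), including the cochaperone Bag3 (0.36 ± 0.08). The heat shock call was lost without desipramine array 5 or 6 or fluoxetine array 1, 2, 4 or 6, at 0.0529 to 0.121.

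Both antidepressants changed 142 probes in the same direction, 101 higher and 41 lower, where independent lists would share 8.46 and 3.88. Opposite changes were called at 4 probes, those of Ctsk, lower with desipramine and higher with fluoxetine, and the unnamed probes ILMN_1364727, ILMN_1369851 and ILMN_1372814, of which the last 3 were named after their values were seen. With the untreated arrays divided between the drugs the overlap was 19 to 41 probes, with a median of 30.5. Those comparisons had fewer untreated arrays, and the divided sets held different replicate numbers. Both can lower the overlap, so the drop does not measure the share due to common controls. Of the 142 probes, 62 also passed in the same direction with haloperidol and 9 with diazepam, 3 passed in the opposite direction with diazepam alone, and 76 passed with neither drug in either direction. Arrays numbered 1 to 4 alone gave 87, arrays numbered 5 and 6 alone 0, the replicate number as a block 244, and median scaling 41.

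The stricter set, changed by both antidepressants and different from both other drugs in all 4 direct tests, held 28 probes, 25 higher and 3 lower. In this set Epha2 rose most among genes detected in untreated cells, with a mean log2 change of 1.43 over desipramine and fluoxetine. Dusp8, detected on 2 of 6 untreated arrays, followed at 1.29, Cxcl1 at 1.16, Serpinb2 at 1.06, Ptgs2 at 1.04 and Ccn2 at 0.98. The transcription factor gene Maff was detected on all arrays of both antidepressants and on 1 of 6 untreated arrays. Mafk stood at 0.88, as did Sgk1, a kinase induced by serum and glucocorticoids, with a log2 change of 0.81 ± 0.08 for desipramine and 0.96 ± 0.08 for fluoxetine against 0.03 for haloperidol and 0.01 for diazepam. Gdf15 was detected on all arrays of both antidepressants and on 0 untreated arrays. The 3 lower probes were those of Fzd8 (mean -0.77), Smad6 (-0.64) and the unnamed ILMN_1370740 (-0.60), the last named after its value was seen. Gdf15, Dusp8, Mafk and Fzd8 also passed in the same direction with haloperidol against untreated cells (limma, adjusted p from 0.00782 to 0.0443). So did Slc25a25 and Mafg of this set, named after their values were seen. All of these changed less with haloperidol than with either antidepressant, which the rule of the set requires and which is therefore no separate result. The replicate number as a block gave 46 of this kind, median scaling 6, arrays numbered 1 to 4 alone 19 and arrays numbered 5 and 6 alone 0.

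**Figure D5:**
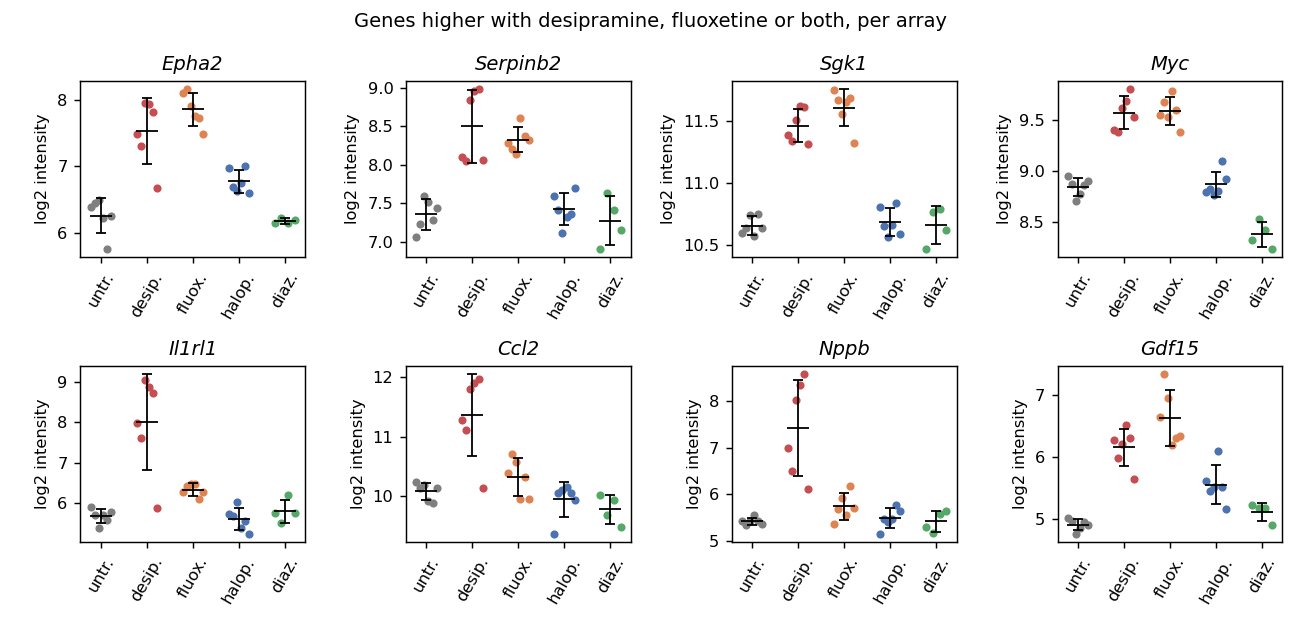
Log2 intensity per array (points), with mean and SD (bars), of 8 genes higher with desipramine, fluoxetine or both. Sgk1 was 0.81 and 0.96 log2 units above untreated cells with desipramine and fluoxetine, while Il1rl1 on desipramine array 6 lay close to the untreated arrays.

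The probes called in the same direction with each of the 4 drugs, all against the same untreated arrays, numbered 8, 3 higher and 5 lower. With 3 untreated arrays for the antidepressants and the other 3 for haloperidol and diazepam the count was 0 to 1, in comparisons of fewer arrays. It was 3 in arrays numbered 1 to 4 alone, 0 in arrays numbered 5 and 6 alone, 13 with the replicate number as a block and 1 under median scaling. Siah2 was higher by 0.81 with desipramine, 1.18 with fluoxetine, 1.16 with haloperidol and 0.62 with diazepam, and Noct by 0.82, 0.72, 0.93 and 0.75. Rasd1 had log2 changes of -0.40, -1.36, -0.56 and -0.92 in the same order, and Btbd3 of -0.50, -0.68, -0.76 and -0.59. The diazepam calls of Siah2 and Noct were lost under median scaling (adjusted p = 0.379 and 0.19). Desipramine, fluoxetine and haloperidol shared 62 probes, 43 of them higher, among them Chac1 and Trib3. With 2 untreated arrays per drug the count was 0 to 4, with a median of 2 over 90 divisions, again in comparisons of fewer arrays. Within numbers 1 to 4 the 3 drugs shared 36 and within numbers 5 and 6 they shared 0, and the count was 117 with the block and 11 under median scaling.

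Across the 11364 probes, which are not independent replicates, the log2 changes against untreated cells of fluoxetine and haloperidol had Pearson r = 0.593, above that of desipramine and fluoxetine (0.409), of haloperidol and diazepam (0.392) and of desipramine and haloperidol (0.330). Fluoxetine and diazepam had r = 0.223 and desipramine and diazepam r = 0.120. The last was 0.0652 without desipramine array 6, 0.183 without untreated array 1, 0.195 without untreated array 6 and 0.227 under median scaling. In simulations of unchanged groups, which hold noise alone, shared untreated arrays gave r between 0.446 and 0.499. Those values follow from the numbers of arrays. They are no baseline for the r above, where drug effects also enter. With the untreated arrays divided between the drugs, the mean r was 0.326 for fluoxetine and haloperidol, 0.194 for the antidepressants, 0.121 for haloperidol and diazepam, 0.114 for desipramine and haloperidol, -0.000408 for fluoxetine and diazepam and -0.0817 for desipramine and diazepam. The divided sets held different replicate numbers. For drugs that hold all numbers, an effect of the number then enters their changes with opposite sign. That lowers r, so the divided values are no unbiased estimate either. The jackknife SE of r was 0.0870 for fluoxetine and haloperidol and 0.115 for the antidepressants.

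Set against haloperidol alone, the antidepressants were higher in Il1rl1 (log2 change 1.57 ± 0.26 SE, 12 against 6 arrays, adjusted p = 0.000304; again mainly through desipramine), Cxcl1 (1.35 ± 0.23) and Inhba (1.18 ± 0.24). Zic2 (-0.98 ± 0.18), Ctsk (-0.98 ± 0.09) and Wfikkn1 (-0.95 ± 0.11) were lower than with haloperidol. Il1rl1, Ctsk and Wfikkn1 also differed between the antidepressants. The count was 596 probes, 320 higher and 276 lower, with 334 in arrays numbered 1 to 4 alone and 5 in arrays numbered 5 and 6 alone, and 333 of the 334 changed in the same direction in the latter. The replicate number as a block gave 1000 and median scaling 167, with 38.3% higher against 53.7%. Called upward were immediate early genes (15 of 27 higher and 2 lower, adjusted p = 1.13e-15; 17 and 2 adjusted over the list alone), NF-kappaB and inflammation genes (8 of 15 higher, adjusted p = 5.81e-11; 10 adjusted over the list alone) and regulators of MAP kinase and G protein signals (8 of 17 higher and 1 lower, adjusted p = 1.5e-06; 8 and 1 adjusted over the list alone). Growth and neurotrophic factors (6 of 17 higher, adjusted p = 1.14e-05; 8 adjusted over the list alone) and cAMP and CREB targets (3 of 17 higher and 1 lower, adjusted p = 0.00525; 5 and 1 adjusted over the list alone) were called upward too, and these 5 lists passed with an estimated correlation, at adjusted p from 8.72e-05 to 0.0253. Also called upward was the integrated stress response list, with 5 of 20 higher, 7 adjusted over the list alone (adjusted p = 0.000187; adjusted p = 0.128 with an estimated correlation). The cell cycle list was called downward with 9 of 26 lower, 14 lower and 2 higher adjusted over the list alone (adjusted p = 3.13e-08; adjusted p = 0.143 with an estimated correlation), including the kinase gene Aurka (-0.41 ± 0.09). Cholesterol synthesis was called downward with 2 of 17 lower, 5 adjusted over the list alone (adjusted p = 0.00784; adjusted p = 0.196 with an estimated correlation), and fatty acid synthesis with 1 of 12 lower, 1 adjusted over the list alone (adjusted p = 0.00235; adjusted p = 0.198 with an estimated correlation).

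Set against diazepam alone, the antidepressants were higher in Ccn2 (log2 change 1.56 ± 0.09 SE, 12 against 4 arrays, adjusted p = 1.99e-13) and Epha2 (1.52 ± 0.16), and Dusp8, detected on 0 diazepam arrays, was at least 2.35-fold higher. Cxcr4 (-1.41 ± 0.20), Atoh8 (-1.29 ± 0.17) and Hexim1 (-1.04 ± 0.14) were lower. Ccn2, Dusp8 and Cxcr4 also differed between the antidepressants. Part of the Ccn2 difference was a fall with diazepam against untreated cells (log2 change -0.59 ± 0.10, limma adjusted p = 0.000769). The same held for Myc, named below (-0.47 ± 0.09, adjusted p = 0.00539). Epha2 and Dusp8 did not pass with diazepam against untreated cells. Of 706 probes 433 were higher and 273 lower; arrays numbered 1 to 4 alone gave 241 and arrays numbered 5 and 6 alone 95, and 235 of the 241 changed in the same direction in the latter. With the replicate number as a block the count was 1186, without diazepam array 6 it was 455, and under median scaling it was 224, with 80.8% higher against 61.3%. The 6 lists called were all upward and all passed with an estimated correlation, at adjusted p from 0.000117 to 0.0156. They were immediate early genes (14 of 27 higher and 2 lower, adjusted p = 6.1e-14; 19 and 3 adjusted over the list alone), with Myc at 1.20 ± 0.08, NF-kappaB and inflammation genes (7 of 15 higher, adjusted p = 2.37e-09; 10 adjusted over the list alone) and the integrated stress response list (9 of 20 higher, adjusted p = 4.81e-08; 10 higher and 1 lower adjusted over the list alone). Regulators of MAP kinase and G protein signals (9 of 17 higher and 1 lower, adjusted p = 9.67e-07; 9 and 2 adjusted over the list alone), circadian clock genes (3 of 11 higher, adjusted p = 9.56e-05; 5 adjusted over the list alone) and growth and neurotrophic factors (4 of 17 higher, adjusted p = 0.000196; 6 adjusted over the list alone) were the others.

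Haloperidol and diazepam differed in Hmox1 (log2 change 1.02 ± 0.12 SE, n = 6 and 4, adjusted p = 1.59e-05) and Atf3 (0.98 ± 0.14), both higher with haloperidol, and Rasl11a, detected on 0 diazepam arrays, was at least 1.64-fold higher. Cxcr4 (-1.47 ± 0.23) and Atoh8 (-1.11 ± 0.19) were higher with diazepam. Cyp1a1, a cytochrome induced by ligands of the aryl hydrocarbon receptor, was detected on 0 haloperidol and 4 diazepam arrays and was at least 1.75-fold higher with diazepam (adjusted p = 0.0355), a call lost without haloperidol array 1, 2, 3, 5 or 6 or diazepam array 1, 5 or 6, at 0.0539 to 0.139. The contrast passed at 261 probes, 175 higher and 86 lower. Arrays numbered 1 to 4 alone gave 50 and arrays numbered 5 and 6 alone 0 in limma (1596 at an unadjusted p under 0.05), where 49 of the 50 changed in the same direction. The count was 672 with the replicate number as a block, 165 without haloperidol array 1, 136 without diazepam array 5, 112 with only these groups in the fit, 123 without the arrays numbered 1, and 71 under median scaling, with 91.5% higher against 67.0%.

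The 3 lists called between haloperidol and diazepam were higher with haloperidol, and 0 of them passed with an estimated correlation. The integrated stress response list had 4 of 20 higher, 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.0334; adjusted p = 0.475 with an estimated correlation), including Atf4 at 0.62 ± 0.09. Its call was lost without haloperidol array 3 or 4 or diazepam array 4 or 5, at 0.0733 to 0.188. Circadian clock genes had 4 of 11 higher, 4 adjusted over the list alone (adjusted p = 0.0218; adjusted p = 0.0812 with an estimated correlation), with Nfil3 at 0.84 ± 0.12, and lost the call without diazepam array 1 (0.0845). The cell cycle list had 1 of 26 higher, 7 adjusted over the list alone (adjusted p = 0.000687; adjusted p = 0.475 with an estimated correlation), and lost the call without diazepam array 4 (0.069), when 1 list was called.

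By fry, which tests whether the genes of a list moved one way on balance and not whether they moved more than other genes, the counts of lists called differed from those of camera. They were 13 with desipramine (12 by camera), 8 with fluoxetine (12), 8 with haloperidol (6), 4 with diazepam (5), 13 for antidepressants against non-antidepressants (9), 8 between the antidepressants (6), 14 against haloperidol (9), 7 against diazepam (6) and 1 between haloperidol and diazepam (3). With each drug the integrated stress response list passed by fry against untreated cells (adjusted p from 4.95e-11 to 0.00749). With desipramine, fluoxetine and diazepam the cell cycle list was called downward by camera and did not pass by fry (0.117, 0.158 and 0.55). Serotonin and noradrenaline genes passed by fry, upward, for antidepressants against non-antidepressants (0.0143) and against haloperidol (0.0312).

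The remaining 7 lists were not called by camera in any of the 9 comparisons. The lowest adjusted p was 0.068 for endoplasmic reticulum chaperones (18 measured) and 0.245 for lysosome and autophagy genes (25). It was 0.387 for serotonin and noradrenaline genes (12), 0.0956 for ribosomal proteins (27) and 0.526 for endothelial markers (3). For markers of oligodendrocytes (7) and of microglia (3) it was 0.526 and 0.486.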

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

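The tests of whether desipramine array 6 was an untreated, fluoxetine, haloperidol or diazepam array were chosen only after the result was seen; the tests of a mislabelled array and of the replicate number were written before. Single arrays far from the rest of their group were sought with Dixon's test in 365 groups of 4 or 6 values (named genes, gene lists and array totals), and 26 values in 7.12% of them lay apart, where chance gives about 1 in 20. Of these, 8 fell on untreated array 1 and 7 on desipramine array 6.

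Desipramine array 6 lay apart in several genes changed by desipramine: Bhlhe40 at 10.46 log2 units, Klf10 at 8.68 and Cxcl1 at 8.86, which desipramine raised, were each the lowest of the 6 arrays, and Ctsk, which it lowered, was the highest at 5.60. The means of its NF-kappaB list (8.36), growth factor list (8.28) and Nrf2 list (10.49) were the lowest. Averaged over the probes changed by desipramine without the array in question, the responses of arrays 1 to 6 were 0.409, 0.360, 0.623, 0.630, 0.564 and 0.172 log2 units. Subtracting the same-numbered untreated array left the SD of these responses at 1.07 times its value, against the replicate number as the cause. On probes that set fluoxetine apart, array 6 stood at 0.508 between desipramine (0) and fluoxetine (1), below the fluoxetine arrays (0.932 to 1.10), against array 6 being a fluoxetine array. On the corresponding scales it stood at 0.524 toward haloperidol, whose arrays lay at 0.800 to 1.18, and at 0.270 toward diazepam, whose arrays lay at 0.828 to 1.14, against an array of either drug. Its response of 0.172 exceeded the highest untreated array (0.134) by less than the SD of the untreated arrays (0.0691). Its integrated stress response list, however, was 0.394 log2 units above the untreated mean, where the untreated arrays lay at -0.0516 to 0.0423 (SD 0.0324), against an untreated array. It remains open whether the array carries a wrong label or had a weak response: 5 of the 6 desipramine arrays were closest to their own group, array 6 being the exception. A sample from outside these groups or a mixed one was not tested, and no biological explanation was tested.

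Untreated array 1 had the lowest means for cholesterol synthesis (10.64) and the cell cycle (9.43) and the highest for immediate early genes (8.74). Among its genes, Klf10 (9.05), Dlx3 (7.08), Pparg (7.91) and Mafk (9.36) were the highest of the untreated arrays and Rnd3 (8.38) the lowest. It lay closer to the diazepam mean (distance 0.290) than to the other untreated arrays (0.306).

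The other values that lay apart from their groups were scattered over the arrays. Fluoxetine array 1 had a mean intensity of 862, against 584 for the next highest fluoxetine array. Rnd3 was highest on fluoxetine array 4 (10.64), and the heat shock list was highest on desipramine array 5 (9.89). Untreated array 5 was lowest for Fhl2 (7.52) and Epha2 (5.76), and untreated array 2 for Larp1b (5.88). With diazepam, Noct was lowest on array 6 (6.63) and Hs3st1 on array 5 (8.26). With haloperidol, Atf3 was lowest on array 6 (6.77), Rasl11a highest on array 3 (6.50) and Cyp1a1 highest on array 4 (5.11).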

How the results depend on the processing

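The fits on arrays numbered 1 to 4 and on arrays numbered 5 and 6, without the arrays numbered 1, with the number as a random effect, and on 3 of the 6 desipramine arrays were chosen after the data were seen; the rest were planned. Of 395 calls for genes named or listed, 0 reversed under any alternative. The replicate block ended 1 of them, the authors' normalized values 19, quantile normalization without background correction 5, no filter on dim probes 40 and median scaling 136. Fits on fewer arrays ended 337 (arrays numbered 5 and 6 alone), 102 (arrays numbered 1 to 4 alone) and 52 (without the arrays numbered 1). Only the compared groups in the fit ended 50, an adjusted p under 0.01 ended 93 and the 1.5-fold minimum 138. Of the 68 list calls, the block ended 4: hypoxia and glycolysis with fluoxetine (adjusted p = 0.0676), neuron markers with haloperidol (0.0521), the cell cycle with diazepam (0.124) and the integrated stress response between haloperidol and diazepam (0.1). Median scaling ended 8 list calls, array weights 6 and the authors' normalized values 3. Leaving out the arrays numbered 1 ended 7 list calls, arrays numbered 1 to 4 alone 9 and arrays numbered 5 and 6 alone 18. The log2 changes from the authors' values had r of 0.980 to 0.994 across probes with those reported. Causes were not tested unless the construction gives them, as fewer arrays or a stricter threshold do. A block for the chip was not run. Signal over background limits dim probes, whose changes are compressed. In the order desipramine, fluoxetine, haloperidol and diazepam against untreated cells, antidepressants against non-antidepressants, desipramine against fluoxetine, antidepressants against haloperidol, antidepressants against diazepam, haloperidol against diazepam, both antidepressants, and the stricter set, the reported probe counts were 635, 426, 424, 90, 813, 942, 596, 706, 261, 142 and 28. Median scaling gave 245, 158, 84, 21, 255, 354, 167, 224, 71, 41 and 6. The replicate number as a fixed block gave 1105, 861, 848, 172, 1276, 1485, 1000, 1186, 672, 244 and 46. As a random effect it gave, for the first 10, 1081, 790, 827, 189, 1279, 1443, 981, 1105, 583 and 229. An adjusted p under 0.01 gave 300, 213, 193, 42, 434, 452, 286, 364, 102, 73 and 15. A change of at least 1.5-fold left 133, 116, 72, 34, 85, 171, 75, 150, 63, 41 and 9. Arrays numbered 5 and 6 alone gave 0, 25, 9, 2, 67, 0, 5, 95, 0, 0 and 0 in limma, where the comparisons at 0 had 842 (desipramine against untreated), 751 (against fluoxetine) and 1596 (haloperidol against diazepam) at an unadjusted p under 0.05. Arrays numbered 1 to 4 alone gave 220 for haloperidol, 17 for diazepam, 453 for antidepressants against non-antidepressants, 334 and 241 for antidepressants against haloperidol and diazepam, 50 for haloperidol against diazepam, 87 for both antidepressants and 19 for the stricter set. Without the arrays numbered 1, fluoxetine gave 283, haloperidol 245 and haloperidol against diazepam 123. With only the compared groups in the fit, diazepam gave 48 and haloperidol against diazepam 112, and with array weights desipramine gave 1058. Over the 20 choices of 3 of the 6 desipramine arrays, the lowest counts were 104 against untreated cells (arrays 1, 2 and 6) and 121 against fluoxetine, and the highest 936 and 1320. The correlation of desipramine and diazepam effects was 0.227 under median scaling and 0.235 on arrays numbered 5 and 6 alone. On the latter the correlation of fluoxetine and diazepam effects was 0.373, and the lists called were 2 with haloperidol, 3 with diazepam and 0 between them.

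Leaving out single arrays gave these ranges, in the same order: 440 to 834, 307 to 436, 300 to 473, 47 to 97, 594 to 921, 605 to 1219, 415 to 725, 455 to 785, 136 to 264, 113 to 147 and 22 to 36. The lists called ranged from 10 to 13, 9 to 12, 4 to 8, 4 to 6, 8 to 10, 5 to 6, 9 to 9, 6 to 6 and 1 to 4. Correlations of effects ranged from 0.328 to 0.451 for desipramine and fluoxetine, 0.253 to 0.388 for desipramine and haloperidol, 0.0652 to 0.195 for desipramine and diazepam, 0.553 to 0.635 for fluoxetine and haloperidol, 0.177 to 0.306 for fluoxetine and diazepam and 0.317 to 0.469 for haloperidol and diazepam. The correlation of desipramine and diazepam effects (0.120) moved by over 1.5 times, to 0.0652 without desipramine array 6, 0.183 without untreated array 1 and 0.195 without untreated array 6. The counts moved by over 1.5 times were 47 for diazepam without diazepam array 5 or 6, 614 and 605 for desipramine against fluoxetine without desipramine array 3 or 4, and 455 for antidepressants against diazepam without diazepam array 6. For haloperidol against diazepam they were 165 without haloperidol array 1 and 136 without diazepam array 5, and 1 list without diazepam array 4.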

Other observations

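The tests of why fluoxetine and haloperidol effects went together, the test of scaling for the integrated stress response list, and the draws within replicate numbers for antidepressants against other drugs, were chosen after the result was seen; the other tests of that list and those of other splits of the arrays were written before. The genes in the next paragraph were chosen after their values were seen.

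Within lists that camera did not call, single genes passed the threshold, some of them upward and some downward. Herpud1, an endoplasmic reticulum protein induced by unfolded proteins, rose by 1.10 ± 0.13 log2 units (SE) with fluoxetine, 0.73 ± 0.13 with haloperidol and 0.57 ± 0.13 with desipramine, and Xbp1, a factor of the unfolded protein response, by 0.31 and 0.27 with fluoxetine and desipramine. In the same list Pdia3, a disulfide isomerase, had a log2 change of -0.47 ± 0.13 with haloperidol (adjusted p = 0.0293) and Manf one of -0.24 ± 0.07 between the antidepressants and diazepam. Of the serotonin and noradrenaline genes, Htr2a, a serotonin receptor, was higher with the antidepressants than with the other drugs by 0.43 ± 0.09 (adjusted p = 0.00126). Against untreated cells Htr2a had a log2 change of -0.43 ± 0.13 with diazepam (limma, adjusted p = 0.138). The difference between drugs is therefore not to be read as a rise with the antidepressants. The oligodendrocyte lineage gene Sox10 was higher with desipramine than with fluoxetine by 0.44 ± 0.12, while Olig1 had a log2 change of -0.73 ± 0.14. The lysosomal protease gene Ctsd had a log2 change of -0.43 ± 0.10 with haloperidol, and Flcn, a regulator of lysosomal signals, rose by 0.46 ± 0.11 with fluoxetine.

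The integrated stress response list was called upward with every drug. With the replicate number as a block, the highest adjusted p of camera over the 4 drugs was 1.18e-07, for diazepam. Diazepam lacks numbers 2 and 3, so for this drug the value argues against the replicate number as the cause. Desipramine, fluoxetine, haloperidol and untreated cells hold the same numbers, so an additive effect of the number cancels from their mean differences. For those drugs the block is therefore no test. Over 3 other scalings the mean change of the list was at least 3.58 times its SE with desipramine, fluoxetine and haloperidol (lowest ratio for desipramine under median scaling, 0.31 ± 0.09), against scaling between arrays for these drugs. For diazepam scaling cannot be told apart: the mean change was 0.17 ± 0.04 and 0.19 ± 0.06 under 2 scalings but 0.08 ± 0.17 under median scaling, 0.507 times its SE. The adjusted p of camera under these scalings, which had been planned as the test, could hardly respond to a shift of all probes and was not used. Against any 3 of the 6 untreated arrays the lowest mean change of the list was 0.21 log2 units (diazepam), against low values on some untreated arrays. For desipramine, fluoxetine and haloperidol a shared response of the cells, rather than these technical sources, may therefore be a candidate explanation, as a hypothesis found and tested on the same data; the lack of a stated vehicle leaves the solvent untested.

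Effects of fluoxetine and haloperidol correlated more than those of the antidepressants. The shared untreated arrays are not excluded, since fluoxetine and haloperidol correlated more in 19 of 20 divisions of these arrays and not in the other. That the uneven desipramine arrays only added noise also stays open: the covariance differed by 0.00420, about its jackknife SE of 0.00404. A difference between the drugs in their biology was not tested apart from these.

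Other splits of the same arrays were fitted to see how often they gave as many calls. For desipramine against untreated cells, fluoxetine against untreated cells and desipramine against fluoxetine, which the replicate number pairs, 32 splits exchanged labels within numbers, and for the rest 100 random splits were drawn. Chance was excluded for the count of probes in each of the 9 comparisons, since 1 split, the real one, reached it in each case. The real and highest other counts were 635 and 228 for desipramine (the latter when only number 6 was exchanged), 426 and 26 for fluoxetine, 424 and 175 for haloperidol, 90 and 24 for diazepam, 813 and 198 for antidepressants against non-antidepressants, and 942 and 488 for desipramine against fluoxetine. They were 596 and 40 for antidepressants against haloperidol, 706 and 399 for antidepressants against diazepam, and 261 and 179 for haloperidol against diazepam. For both antidepressants (142 and 0) and the stricter set (28 and 0) only the real split, 1 of 100, reached the count, but a probe must pass 2 or 6 tests at once there, so other splits give near 0 and the draws say little about these sets. For lists called, 1 of 32 splits was as large for desipramine (12 against 11 in the highest other split) and for desipramine against fluoxetine (6 against 5). For haloperidol (6 against 6) and diazepam (5 against 5) 4 of 100 were as large. These shares lay under 0.05, the limit fixed beforehand. Other splits nevertheless called as many lists or nearly as many, so chance was not taken as excluded for these counts. Nor was it excluded for fluoxetine (12 against 12, 2 of 32) or antidepressants against non-antidepressants (9 against 12, 6 of 100). The same held for antidepressants against diazepam (6 against 9, 10 of 100) and haloperidol against diazepam (3 against 7, 26 of 100). For antidepressants against haloperidol 3 of 100 of these draws were as large (9 against 10). Among draws within numbers 7 of 100 were (9 against 12), so chance was not excluded there. Draws within numbers did not exclude it for antidepressants against non-antidepressants (9 against 12, 7 of 100) or against diazepam (6 against 7, 19 of 100) either. For probes, draws within numbers excluded chance in all 3: the highest others were 242 against non-antidepressants, 33 against diazepam and 995 against haloperidol, where 2 of 100 reached 596. The split with 995 put all 6 desipramine arrays in the place of haloperidol, so it set desipramine against fluoxetine and haloperidol, a difference between drugs.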
